A study of Mus musculus with 2 samples.

How the data were processed

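Total RNA of 2 mouse mesoangioblast clones was measured, with 1 Affymetrix U74A array for clone D16 and 1 for clone D351. The values are intensity values per probe set on a linear scale, as deposited by the authors in the table of the series. The software and the scaling and background method that made them are not given in the sources used here, and no detection call was used. The 2% trimmed mean was 100.1 in both arrays, so the deposited values appear to have been scaled to a common target. Medians were 31.8 for D16 and 29.7 for D351. No genome build is named with the values.

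Probe sets were named through a platform annotation table. It belongs to version 2 of the array, while the labels read U74A, and the version was not checked further. Symbols were updated by Entrez gene number to the RefSeq annotation of mouse assembly GRCm38.p6. The same annotation gave the chromosome and order of genes; none of its coordinates is printed. Of 12422 non-control probe sets, 10833 had a single symbol (10817 updated, 16 kept as in the table), 396 had several and 1193 had none. Probe sets with several or no symbols named no gene. The 66 control probe sets were left out of all results on genes.

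The arrays were scaled to the same median log2 level over non-control probe sets at or above the floor in both, with factors of 0.983 for D16 and 1.02 for D351. The floor was the 40th percentile of the scaled non-control values, an intensity of 17.5. Values below it were set to it before the log2 ratio of D351 over D16 was taken. A gene at the floor in 1 clone has a lower bound only, written as at least N-fold, and a gene below it in both has no ratio. A ratio whose lower level lies just above the floor is written as measured, but its size rests on a value near the floor. Each of the 8251 genes was represented by its probe set with the highest mean level. For named genes, other probe sets at or above the floor are mentioned where their log2 ratio differs in sign or by over 1. Probe sets with the suffix f or s can match transcripts of other genes, and among the genes named in the report or here Actg2, Actc1, Cnn1, Mgp, Fas, Cd68, Rpl41 and H2-D1 were measured by such probe sets alone, while Eif2s3y, below the floor, has no other kind.

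With 1 array per clone no test, standard error or p-value was possible. Differences were counted at 2-fold or more. The number of arrays limits the precision, and the spread between probe sets of one gene was used as the measurable part of the error. The 30 gene lists and the design were fixed before the data were examined. For each list with at least 5 measured genes, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean level in 10 bins. A list was called outside below a percentile of 2.5 or above 97.5. This describes these arrays and is not a test of the clones.

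The genes named in the text were set by a rule fixed beforehand: the 10 highest and 10 lowest ratios among genes measured in both clones, the 5 largest bounds in each direction, up to 4 genes of each list with the largest ratio of at least 2-fold (or up to 2 members with the highest level where none reached it), the genes of the X and Y list, a set of marker genes, and the 5 genes with the highest mean level. Those last were Rpl41, S100a6, Eef1a1, Lgals1 and Rplp0. Genes outside the rule are marked where they appear.

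The same functions were tested on simulated arrays made from the real levels, with probe error of the measured size. Of 50 genes given a log2 ratio of 3, 100% were found at 2-fold or more in the right direction, and also 100% of 50 genes given -3. At 1.5 and -1.5 the shares were 82% and 72% of 50 genes each, and 4.69% of 5437 unchanged genes passed 2-fold, over 5837 genes in all. All 10 lists of 20 genes shifted by 0.8 lay outside the random range, as did 2.5% of 200 unchanged lists. These shares were not split by level, so they cannot be carried over to genes near the floor. The measured SD between probe sets of a gene was 0.57 at the lowest levels (269 genes) and 0.43 at the highest (269 genes).

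Alternatives covered the scaling (as deposited, quantile, intensity-dependent loess), the floor (25th and 60th percentile, none, or a pseudocount), the probe set rule, the size threshold and the list statistic. Chosen after seeing the data were a scaling on the hybridization controls and ratios taken relative to the median of each chromosome. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.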

Results

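Mesoangioblasts are vessel-associated progenitor cells that can be grown from the embryonic dorsal aorta and can give rise to several mesodermal cell types. RNA of 2 mouse mesoangioblast clones, D16 and D351, was measured on Affymetrix U74A arrays, with 1 array for each clone. Both clones came from dorsal aorta of C57BL6 embryos at embryonic day 9.5. The tissue was kept as an explant for 5 days, then single cells were cloned over growth-arrested embryonic fibroblasts in medium with 20% fetal calf serum and later expanded on gelatin. Each array held 12488 probe sets, 66 of them controls. At or above the intensity floor of 17.5 were 7528 non-control probe sets in D16 (60.6%) and 7369 in D351 (59.3%). Without replicates there is no test of any gene, and all differences are sizes measured between these arrays.

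The comparison asks how far 2 clones derived in the same way differ in gene expression. The submitters' keywords name smooth muscle differentiation and stem cells. Genes of the extracellular matrix, of smooth muscle, of inflammatory signalling and among the p53 targets and cell cycle inhibitors had higher levels in D351, while genes of the cell cycle had higher levels in D16. The median gene of the extracellular matrix list had a log2 ratio of D351 over D16 of 1.07 (38 genes), and that of the cell cycle list had -1.09 (37 genes). The chemokine gene Ccl7 was 58.1-fold higher in D351, with a D16 level of 19.9, near the floor. The non-coding imprinted gene Meg3 was at least 116-fold higher in D351. In the other direction, the imprinted gene Mest was at least 42.3-fold higher in D16, and Cd34, which encodes a surface protein of vascular and haematopoietic progenitors, at least 27.2-fold.

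Of 6100 genes at or above the floor in at least 1 clone, 641 were at least 2-fold higher in D351 and 538 at least 2-fold higher in D16. In 148 of the former and 101 of the latter the other clone was below the floor, so the ratio is a lower bound. At 4-fold or more there were 138 genes higher in D351 and 77 higher in D16. The remaining 4921 genes (80.7%) lay within 2-fold. Across the 5196 genes measured in both clones, the log2 levels correlated with Pearson's r = 0.865 and Spearman's rho = 0.850; genes are not independent replicates. The error that can be measured is the spread between probe sets of one gene, an SD of 0.52 on the log2 scale over 806 genes. Of 127 such genes at least 2-fold apart by their brightest probe set, the second probe set had the same sign in 76.4% and was also at least 2-fold apart in that direction in 37.8%. Probe error of that kind alone gave 263 genes past 2-fold among the 5196, against 930 observed, and it leaves out the spread between cultures. With the arrays scaled on their hybridization controls instead, the counts were 1203 and 246, so that 83% of the genes past 2-fold were higher in D351 against 54.4% in the main setting, and the median log2 ratio of all genes moved from -0.03 to 0.34.

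**Figure D1:**
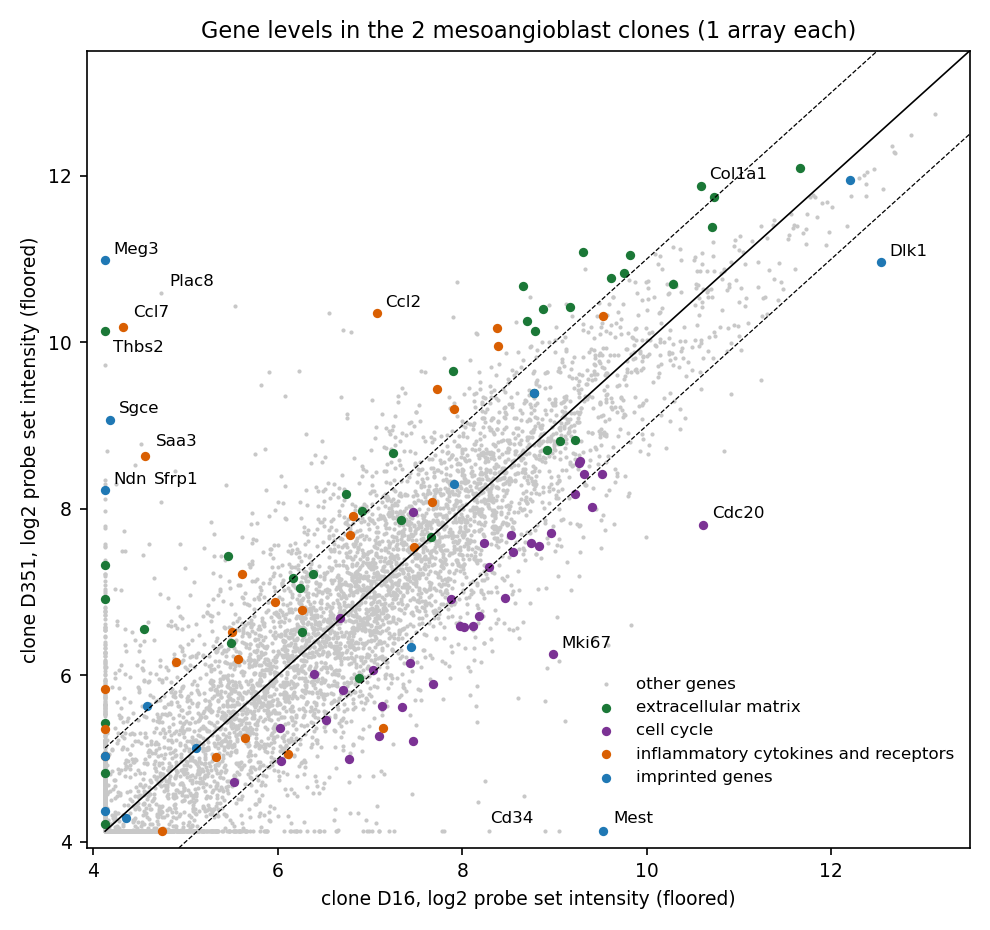
Log2 probe set intensity of each gene in clone D16 (x axis) and clone D351 (y axis), 1 array each, with values below the floor drawn at it. The solid line marks equal levels and the dashed lines 2-fold differences. Cell cycle genes (purple) lie mostly below the solid line (23 of 37 at least 2-fold higher in D16) and extracellular matrix genes (green) mostly above it (22 of 38 at least 2-fold higher in D351).

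Extracellular matrix genes had higher levels in D351. Of 38 measured genes, 22 were at least 2-fold higher in D351 and 0 in D16, and the list median of 1.07 had a percentile of 100 among matched random lists, whose central 95% ran from -0.26 to 0.24. Thbs2, a matricellular thrombospondin, was at least 64.1-fold higher in D351, and the microfibril gene Mfap2 at least 9.14-fold. The collagen gene Col5a1 was 4.04-fold higher, at levels of 405 in D16 and 1636 in D351. Lama5, a laminin chain, was at least 6.92-fold higher by its brightest probe set, with a log2 ratio of 0.28 for another. Among matrix proteases and their inhibitors, 8 of 22 genes were at least 2-fold higher in D351 and 1, the urokinase receptor gene Plaur, at least 2-fold higher in D16 (2.92-fold). The list median was 0.51 (percentile 99.8). Adam19, a membrane metalloprotease, was 5.04-fold higher in D351, Timp2, a metalloprotease inhibitor, 4.30-fold and Mmp11 3.66-fold.

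The list of embryonic fibroblast genes, fixed because the clones were started on fibroblast feeders, had a median of 1.05 (percentile 100). Its shift came from the 12 of its 20 measured genes that are also in the matrix list (median 1.20), while the other 8 had a median of -0.26 (percentile 16.7), with 5 of them lower in D351. All 20 were at or above the floor in both clones. At least 2-fold higher in D351 were 11, among them the proteoglycan genes Ogn (4.04-fold) and Lum (4.02-fold, with a D16 level of 23.4, near the floor). In the other direction, S100a4, a fibroblast marker, was 4.42-fold higher in D16, with levels of 1834 and 414. Thy1, a surface marker of fibroblasts, measured 1534 in D16 and 1041 in D351.

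Smooth muscle genes were also higher in D351, with 8 of 18 measured genes at least 2-fold higher there, 0 at least 2-fold higher in D16 and a list median of 0.90 (percentile 100). The enteric smooth muscle actin gene Actg2 was 10.8-fold higher in D351 by its only probe set, of a kind that can share targets with other genes. The actin-binding calponin gene Cnn1 was at least 9.0-fold higher there and Mylk, which encodes myosin light chain kinase, 5.07-fold. Csrp1, a cytoskeletal LIM protein gene, was 3.16-fold higher. Acta2, the vascular smooth muscle actin gene, measured 939 in D16 and 1686 in D351, a ratio of 1.79. Des, the intermediate filament gene of muscle, was below the floor in D16 and at 41.0 in D351. The list of skeletal and cardiac muscle genes had a median of -0.03 (percentile 58.4), with Actc1 2.27-fold higher in D351, also by a probe set that can share targets, and the cardiac transcription factor gene Gata4 2.43-fold higher in D16. Myod1, the skeletal muscle determination gene, measured 41.7 and 44.7.

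Inflammatory cytokine and receptor genes had a median of 0.96 (percentile 100), with 13 of 26 at least 2-fold higher in D351. Besides Ccl7, the acute phase gene Saa3 was 16.8-fold higher, with a D16 level of 23.7, near the floor. The monocyte chemoattractant gene Ccl2 was 9.72-fold higher. Cxcl12, a chemokine that guides progenitor cells, was 3.48-fold higher, with log2 ratios of 3.19 and 2.34 for its other probe sets. At least 2-fold higher in D16 were 2 genes, Ptgs2 and Il13ra1 (log2 ratios of -1.76 and -1.06), named after their values were seen. Of 31 interferon response and MHC class I genes, 12 were at least 2-fold higher in D351 and 3 in D16, with a median of 0.54 (percentile 99.9). The interferon-induced genes Ifit3, Irgm1 and Isg15 were 5.95-fold, 4.90-fold and 4.35-fold higher in D351. Ifi202b, also interferon-inducible and known to vary in level between mouse strains, went the other way and was at least 12.8-fold higher in D16. Both clones are labelled C57BL6, and their strain background was not tested. Mx2 and the class I gene H2-D1, named after their values were seen, had log2 ratios of -1.59 and -1.17, but the other probe sets of H2-D1 had 1.82 and -2.47.

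Cell cycle genes showed the opposite direction. Of 37 measured genes, 23 were at least 2-fold higher in D16 and 0 in D351, and the list median of -1.09 lay below all 10000 matched random lists (percentile 0). Cdc20, an activator of the anaphase-promoting complex, was 6.99-fold higher in D16 (levels of 1567 and 224), the centromeric histone gene Cenpa 4.78-fold and the spindle checkpoint kinase gene Bub1 3.55-fold. Mki67, the proliferation marker, was 6.61-fold higher by its brightest probe set, while another of its probe sets had a log2 ratio of 0.29. The list of p53 targets and cell cycle inhibitors had a median of 1.15 (percentile 100), with 9 of 17 genes at least 2-fold higher in D351. Perp and Fas, p53 targets in cell death, were at least 6.44-fold and at least 6.04-fold higher in D351. Cdkn2a, the locus of the p16 and p19 inhibitors, was 5.08-fold higher there, with a D16 level of 19.2, near the floor. The single gene of this list that was at least 2-fold higher in D16 was the inhibitor gene Cdkn2c (3.65-fold).

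Immediate early genes had a median of -0.53 (percentile 0.32). At least 2-fold higher in D16 were 6 of 21, including the nuclear receptor gene Nr4a1 (3.05-fold), Ier3 (3.04-fold) and Jun (2.80-fold). Dusp1 and Ccn2, named after their values were seen, were at least 2-fold higher in D351 (log2 ratios of 1.04 and 1.33). Haematopoietic genes had a median of -0.50 (percentile 1.93), close to the limit of 2.5. Only 13 of the 28 on the array were measured, 1 past 2-fold each way: Gata2 was 2.06-fold higher in D16, and the macrophage gene Cd68 at least 2.11-fold higher in D351. Both calls depended on the setting: with the list mean in place of the median, the immediate early list (-0.32) and the haematopoietic list (-0.23) lay inside the random range. In all, 10 of 29 lists lay outside the central range, 7 higher in D351 and 3 higher in D16, where 1.45 would be expected by chance.

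**Figure D2:**
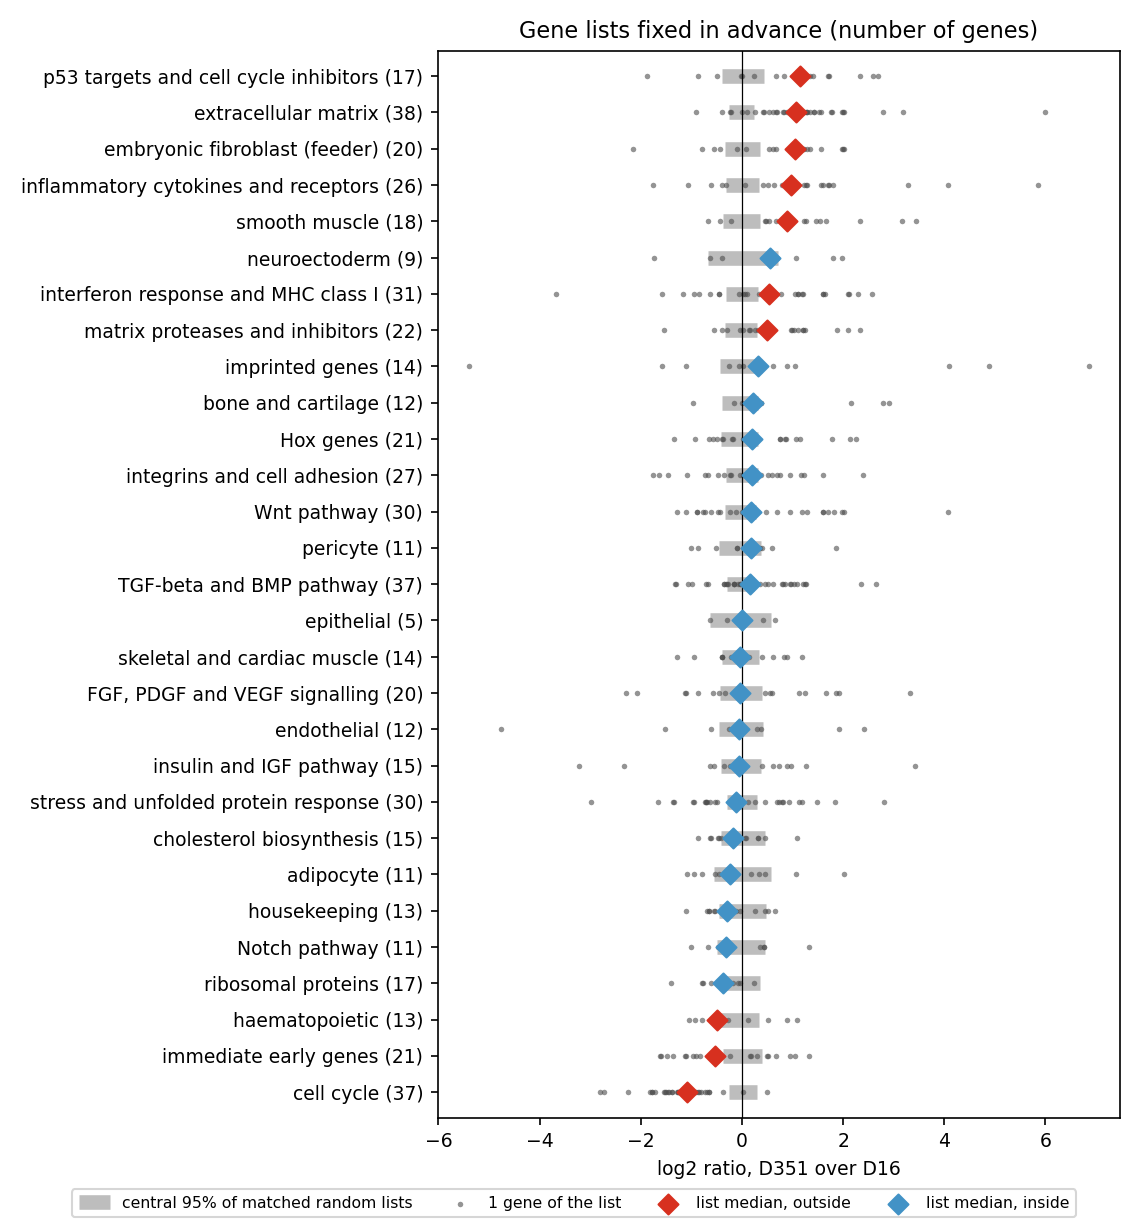
Log2 ratio of D351 over D16 (x axis) for 29 gene lists (rows, with the number of measured genes). Small points are genes, diamonds are list medians (red when outside the grey central 95% of matched random lists, blue when inside). The cell cycle median of -1.09 is the lowest and the p53 and inhibitor median of 1.15 the highest.

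Among the largest single differences, higher in D351 were Plac8 (58.1-fold), the serine protease inhibitor gene Serpinb6a (29.9-fold), the sarcoglycan gene Sgce (29.6-fold), the sulfhydryl oxidase gene Qsox1 (23.4-fold, another probe set with a log2 ratio of at least 0.53) and the extracellular glutathione peroxidase gene Gpx3 (19.1-fold). The secreted Wnt regulators Sfrp1 and Rspo2 were 16.8-fold and 16.7-fold higher, and F3, which encodes tissue factor, 14-fold. Below the floor in D16 were the matricellular gene Ccn3 (at least 48.5-fold higher in D351), Tmem14c (at least 18.6-fold) and the pyruvate dehydrogenase kinase gene Pdk4 (at least 17.9-fold).

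Higher in D16 were Cox6a2, a muscle form of a cytochrome c oxidase subunit (17.3-fold), Epb41l4a (12.9-fold), the membrane-cytoskeleton linker gene Ezr (11.4-fold), the IGF-binding protein gene Igfbp4 (9.31-fold, another probe set with a log2 ratio of -1.03), the muscle enolase gene Eno3 (9.30-fold) and Fam107b (9.21-fold). The metallothionein gene Mt2 was 7.91-fold higher in D16, D17H6S56E-5 7.35-fold and the haem synthesis gene Alad 7.34-fold. Near the floor in D351 were Cox6a2 (23.5), Epb41l4a (22.3) and D17H6S56E-5 (23.8), so the size of their ratios is uncertain too. Mtm1 was 12.6-fold higher in D16 by a probe set that can share targets with other genes, but its other probe set had a log2 ratio of 0.20. Below the floor in D351 were Msln, which encodes mesothelin (at least 30.2-fold higher in D16), and the acyl-CoA thioesterase gene Acot1 (at least 17.9-fold).

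**Figure D3:**
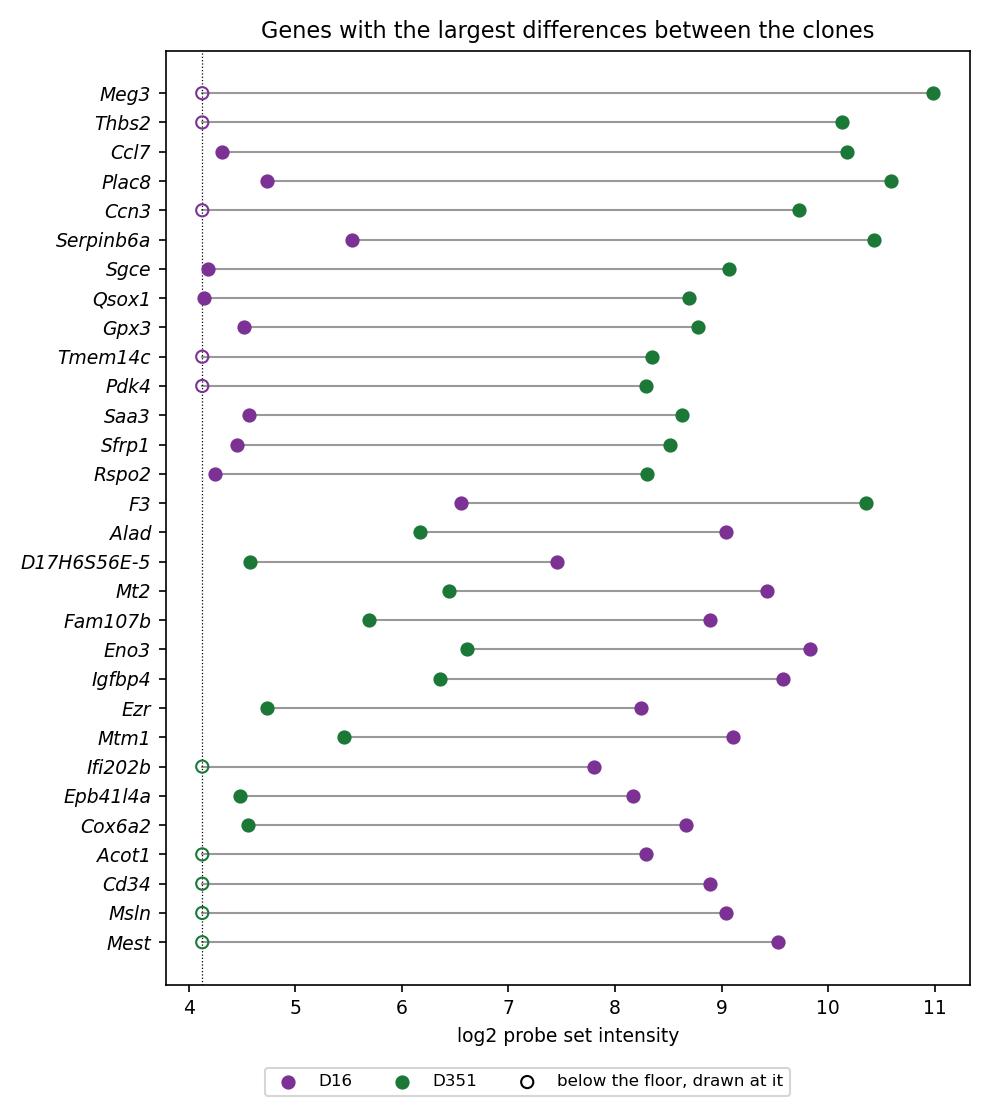
Log2 probe set intensity (x axis) in clone D16 (purple) and clone D351 (green) for the genes with the largest differences, 1 array per clone. Open circles are values below the floor, drawn at the dotted line. Meg3 at the top is at least 116-fold higher in D351 and Mest at the bottom at least 42.3-fold higher in D16.

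Among markers named beforehand, Pdgfrb, a receptor of pericytes and other mesenchymal cells, was 3.62-fold higher in D351 (54.3 and 197), while Pdgfra measured 762 in D16 and 714 in D351, with a log2 ratio of -1.54 for another probe set. Kit and Kdr, receptors of blood and endothelial progenitors, were below the floor in both clones. The endothelial gene Pecam1 was near the floor, at 30.8 and 20.3. The endothelial list had a median of -0.05 (percentile 51.9): Thbd and Flt1 were at least 5.34-fold and at least 3.78-fold higher in D351, against Cd34 (a log2 ratio of at most -3.26 for another probe set) and the arterial ephrin gene Efnb2 (2.85-fold higher in D16). Xist, the RNA that coats the inactive X chromosome, was below the floor in D16 and at 71.8 in D351. The Y-linked genes Kdm5d, Eif2s3y and Uty were below the floor in both, and that list had too few measured genes for a percentile.

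Several signalling lists held large differences in both directions with medians inside the random range. In the Wnt list (median 0.18, percentile 91.4) the antagonist genes Sfrp4 and Dkk3 were at least 3.56-fold and 3.92-fold higher in D351. Dkk3 had a D16 level of 21.8, near the floor. In the growth factor list of FGF, PDGF and VEGF signalling (median -0.03, percentile 49.7), the lymphangiogenic factor gene Vegfd was 10.1-fold higher in D351, whereas the feedback phosphatase gene Dusp6 was 4.89-fold higher in D16. In the insulin and IGF list (median -0.06, percentile 43.4), the protease gene Htra1 was 10.7-fold higher in D351, against Igfbp6, which was 5.02-fold higher in D16. In the TGF-beta and BMP list (median 0.15, percentile 90.9), Inhbb and Ltbp1 were at least 6.25-fold and 5.12-fold higher in D351, and the BMP target genes Id1 and Id2 were 2.48-fold and 2.51-fold higher in D16. The Notch list had a median of -0.32 (percentile 11.2).

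Imprinted genes had a median of 0.32 (percentile 94.9) and wide differences each way: besides Meg3, Sgce and Mest, the growth suppressor gene Ndn was at least 17.1-fold higher in D351. Among bone and cartilage genes (median 0.22, percentile 93.3), the calcification inhibitor gene Mgp was 6.91-fold higher in D351 and the homeobox gene Msx2 at least 7.5-fold. Hox genes had a median of 0.20 (percentile 93.2), with Hoxd8 4.77-fold and Hoxb5 at least 4.42-fold higher in D351 and Hoxa2 2.54-fold higher in D16. Integrins and adhesion genes had a median of 0.20 (percentile 90.0), with Itgb5 5.24-fold higher in D351 (a log2 ratio of 0.87 for another probe set) and Itga6 at least 3.37-fold higher in D16. The neuroectoderm list had a median of 0.56 (percentile 94.9), the pericyte list 0.18 (percentile 86.9), the adipocyte list -0.23 (percentile 20.7) and the epithelial list -0.01 (percentile 57.3). Stress and unfolded protein response genes had a median of -0.12 (percentile 22.0), with the heat shock gene Hspa1a 6.99-fold higher in D351. The D16 level of Hspa1a, 18.8, was near the floor. Medians were -0.18 for cholesterol biosynthesis (percentile 21.3), -0.37 for ribosomal proteins (percentile 3.65) and -0.30 for housekeeping genes (percentile 9.17). With the arrays scaled on their hybridization controls, which raised the median of all genes to 0.34, all 11 lists that had a negative median inside the random range had a positive one.

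Control probe sets on each array measure RNA integrity and hybridization. The ratio of the 3' to the 5' probe set of Actb was 1.81 in D16 and 1.37 in D351, and that of Gapdh was 1.56 and 1.44. That of pyruvate carboxylase, at low levels, was 2.68 and 3.39. The 9 hybridization control probe sets had a median log2 ratio of -0.39, with a range from -0.50 to 0.01.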

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

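Control probe sets and probe sets without a gene name lie outside the comparison of genes. The control probe set MURINE_b1, for a murine B1 repeat, was 2.35-fold higher in D16, at levels of 5803 and 2471. The control probe set MUR_b2, for a murine B2 repeat, was 3.50-fold higher in D16, at 418 and 119, while the brighter control MURINE_B2 was 1.84-fold higher in D16, at 7217 and 3916. The control probe set MurFAS was 5.08-fold higher in D351, at 22.3 and 113, the same direction as the gene Fas. Among probe sets without a gene name, 43 were at least 2-fold higher in D351 and 46 at least 2-fold higher in D16.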

How the results depend on the processing

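No paired analysis was possible because each clone has 1 array, and for the same reason no replicate could be left out. Scaling on the hybridization controls and ratios relative to each chromosome's median were chosen after seeing the data. Of 403 list values under the alternatives, medians except where the list mean was used, 377 stayed on the same side of the random range as in the main setting. Of 1392 values of named genes, 1262 stayed within the probe set spread, 129 moved by more and 1 reversed. A change of sign was counted as reversed only for genes at least 2-fold apart in the main setting. Genes closer together could change sign without being counted. The reversed gene, Mtm1, had a log2 ratio of 0.20 without probe sets with the suffixes f, r, i and x, against -3.65. The cell cycle value ranged from -1.20, which is the list mean, to a median of -0.70. The value of the extracellular matrix ranged from 0.87 to 1.46 and that of smooth muscle from 0.82 to 1.29. The cause was not tested for any change below, except that thresholds and floors change counts by construction.

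Genes higher in D351 and in D16 numbered 1285 and 1277 at 1.5-fold, 251 and 158 at 3-fold, 371 and 354 with the floor at the 60th percentile, 1148 and 1254 with no floor, and 1203 and 246 with equal hybridization controls. With the floor at the 25th percentile, 870 were higher in D16. The correlation was 0.880 with the floor at the 25th percentile, 0.831 at the 60th, 0.894 with no floor and 0.914 with a pseudocount. The haematopoietic list came to lie inside the random range with equal hybridization controls (-0.16), the 25th percentile floor (-0.35) and a pseudocount (-0.19). With no floor (-0.47), the list mean (-0.23) or genes measured in both clones (-0.41) it lay inside too. The suffix alternative left out probe sets with the suffixes f, r, i and x but kept those with s. With it, or with 5 bins, the haematopoietic list came to lie inside at the same median of -0.50. The immediate early list did so with the 60th percentile floor (-0.25), a pseudocount (-0.31), no floor (-0.38) and the list mean (-0.32). Ribosomal proteins came to lie outside with the 25th percentile floor (-0.37), a pseudocount (-0.34), no floor (-0.36), 5 bins (-0.37), the list mean (-0.41) and ratios relative to the chromosome (-0.40). Imprinted genes did so with the 25th percentile floor (0.48) and the list mean (0.76), neuroectoderm with the 60th percentile floor (0.63) and genes measured in both clones (0.62), TGF-beta and BMP with the 60th percentile floor (0.41), and the list means of the Wnt pathway (0.43) and of bone and cartilage (0.68). Skeletal and cardiac muscle, with 5 genes left, also came to lie outside, at 0.56, with the 60th percentile floor. Low signal limits the 2151 genes below the floor in both clones, which have no ratio.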

Other observations

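Gene families were defined by symbol after the data had been seen, so a family can hold a gene that only shares the symbol, and some of their genes are also in the fixed lists. The family members named here were named after their values were seen. Of 30 families, 7 lay outside matched random lists. The 1.5 expected by chance would hold only for families fixed beforehand, so the count is no evidence against chance. The 16 aminoacyl tRNA synthetase genes had a median of -0.69, with 3 at least 2-fold higher in D16; all 16 had lower values in D351 in the main setting, Mars1 by almost nothing (-0.0027), and 13 with equal hybridization controls. Of them Lars, Vars and Wars were lowest (-1.62, -1.34 and -1.31). The 7 Mcm symbols, mostly of the replicative helicase, had a median of -1.27, but 5 of them are in the cell cycle list. Mitochondrial ribosomal proteins (60 genes, -0.28) and translation initiation factors (36 genes, -0.26, with a percentile of 2.49 at the limit of 2.5) were shifted less. With equal hybridization controls, which raised the median of all genes to 0.34, their medians were 0.09 and 0.13, or -0.25 and -0.21 relative to all genes.

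Aldehyde dehydrogenase genes had higher values in D351, with a median of 1.01 over 8 genes. Aldh1a1, which makes retinoic acid, had a log2 ratio of at least 2.33 (another probe set, near the floor, had at most -0.15) and the mitochondrial Aldh2 one of 1.92, while Aldh7a1 was higher in D16 (-1.47). Cathepsins, lysosomal proteases, had a median of 0.78 over 9 genes, 4 of them in the list of matrix proteases, with bounds of 3.08 for Ctsh and 2.86 for Ctsf. Annexins, which bind membranes with calcium, had a median of 0.69 over 8 genes, with 1.51 for Anxa7 and -1.01 for Anxa3.

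In the patterns that follow, the tests of gene length and density, of the preset lists, and the first test of gene clusters were set before their results were seen; the other tests were chosen afterwards.

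The cell cycle list was lower in D351. Its median stayed below the matched random lists under all 5 scalings, at -0.70 where it was nearest to 0. Scaling by a constant moves the list and the random lists alike. A level-dependent bias would also move them much alike, since the random lists were matched on mean level. The main median of -1.09, against a lower end of -0.26 for these lists, therefore argues against such a bias. The medians of -1.18 and -1.13 under quantile and loess scaling add little to that. For unequal chromosome copies, the list median was -1.10 after the median of each chromosome was taken off. That outcome was fixed in advance, since chromosome medians ran only from -0.30 to 0.38. Whole-chromosome shifts of that size are too small to account for the shift of the list. Larger shifts of chromosome segments were not taken off, so for segments the value cannot decide. Carry-over of growth-arrested feeder fibroblasts into D351 stays open: of 20 embryonic fibroblast genes, the 12 also in the matrix list were all higher in D351, but of the other 8 only 3 were higher and 5 were lower, S100a4 among them, and there is no feeder array to give their levels. A difference in proliferation between the clones or their cultures is a further hypothesis, untested here.

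Some imprinted genes lay far apart between the clones: the mean absolute log2 ratio of 1.96 over 14 genes rests on 4 of them, Meg3, Mest, Sgce and Ndn, and that of the other 10 was 0.62 (percentile 64.1). Chance stays open, since the list median fixed beforehand had a percentile of 94.9, and the percentile of 100 for the mean absolute ratio comes from a statistic chosen after the values were seen, by which 14 of 29 lists lay above the random range. Other measured probe sets of Meg3, Ndn and Peg3 had log2 ratios of at least 0.55 in the same direction. Error of a probe set is argued against for Meg3 and Ndn, whose other probe sets had 5.94 and at least 3.33. The smallest value, 0.55, was that of Peg3 and is close to the probe set SD of 0.52, so it cannot decide for Peg3. Nor can probe set error be told apart for Mest, Sgce and Dlk1, which have 1 probe set each (Peg3 and Dlk1 were named after their values were seen). Chromosome copy number is argued against for Meg3 and Dlk1, neighbours on chromosome 12, whose log2 ratios differed by 8.43 in opposite directions (6.86 as a bound, and -1.57). A difference in imprinting or in cell state between the clones may account for it, as a hypothesis that these arrays do not test.

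Median ratios differed between chromosomes: 10 of 20 lay outside matched random gene sets where 1 would be expected by chance, with chromosomes 7, 4, 18 and 17 lower in D351 (medians of -0.30, -0.30, -0.29 and -0.26) and 10, X, 1, 9, 11 and 6 higher (0.38, 0.22, 0.17, 0.13, 0.12 and 0.09). Gene length or density is argued against, since 10 stayed outside after regression. The preset lists are argued against too, since 10 stayed outside without their genes, which were only 536 of 6092. All 10 kept their sign relative to all genes under 5 scalings. Scaling by a constant moves all genes alike, so only quantile and loess scaling could change that sign. Under these it argues against a level-dependent bias. For gene clusters, 7 of the 10 had all 3 equal parts of their gene order on the same side of the median of all genes. Chromosomes 4, 9 and X had 1 part on the other side, at 0.13, -0.0049 and -0.05 relative to that median. The count of 7 met the bound set beforehand. That bound, however, counted parts close to that median, such as the last part of chromosome 11, at 0.02 relative to it. A stricter test, requiring each part to lie outside matched random sets, was added after that result. On 3 chromosomes (7, 10 and 18) it argues against clusters confined to 1 or 2 parts. Clusters in every part would pass the test as well, so it cannot decide on those. Chromosome 18 passed narrowly, with percentiles of 2.02 and 1.6 in its first 2 parts. On the other 7, clusters and a changed segment cannot be told apart. Unequal chromosome copies in the cultured clones are a hypothesis, with no karyotype or DNA measurement here to test it. Whether the shifts have the size of a copy change was not tested. Within chromosomes they were uneven: relative to all genes, the parts of chromosome 4 lay at -0.28, -0.75 and 0.13. Those of chromosome 10 lay at 0.69, 0.30 and 0.20. On chromosome 6 each part lay inside the matched random sets (percentiles 80.5, 96.1 and 75.8).

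The high level of Msln in D16 raised the hypothesis of a mesothelial character of D16. Of 14 further mesothelial markers, chosen after Msln was seen, 10 were on the array. In D16, 3 were at or above the floor, Upk3b, Calb2 and Pdpn at 23.2, 23.8 and 122, while 7 were below it, Wt1, Krt7, Krt8, Krt18 and Krt19 among them. Only 2 markers were bright enough in either clone to show a 2-fold difference over the floor, Pdpn (99.8 in D351) and Gata6, which went the other way (9.04 in D16 and 50.3 in D351, at least 2.88-fold higher). With so few bright markers these values neither exclude the hypothesis nor speak for it.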
